A study of Homo sapiens with 16 samples.

How the data were processed

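Chromatin accessibility was measured by ATAC-seq in 16 libraries from the head and neck squamous carcinoma lines Cal33 and SAS. Per the series' design text, cells received a non-targeting siRNA or siRNA against ITGA7, were placed in laminin-rich matrix at 24 h and gave nuclei at 48 h after transfection. Per the labels' growth and treatment protocols, the siRNA was a pool and the matrix was at 1.0 mg/mL, but those texts speak of RNA work, so these 2 details are not certain for the ATAC-seq cultures. The 4 groups, Cal33 siControl, Cal33 siITGA7, SAS siControl and SAS siITGA7, each held 4 independent biological replicates. The transposase reaction was followed by paired-end sequencing with reads of 100 bp. Library fragment sizes given in the labels ran from 205 to 230 bp. Per the labels, 5 Cal33 libraries had 1 sequencing run each and 3 had 2, and each of the 8 SAS libraries had 1. Whether libraries shared a run is not given in the sources used here.

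The authors deposited a raw count per peak and library for a common set of 164980 peaks, per the file headers, and these whole-number counts were the basis of every test. The deposited normalized signal was the raw count divided by 1 factor per library, as the values show. How that factor was made is not given in the sources used here, so the normalized signal was not used in a test. The submitters' processing notes name bcl2fastq 2.20.0 and the build hg38 or GRCh38. The aligner, the peak caller, the counter, any shift of reads for the transposase and the treatment of duplicates are not given in the sources used here. A count is therefore not known to be an independent molecule, and the errors of counts stated here cover the spread between libraries. Peaks were shared by both lines, so that a peak open in 1 line only was also counted in the other.

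The deposited annotation gives each peak a class (promoter, exon, intron, transcription end, intergenic) and the Ensembl identifier of the gene with the nearest start. No symbol is paired with these identifiers. They were matched by position to RefSeq genes of GRCh38.p14, from the starts and peaks that each identifier covers, and 20505 of 45291 identifiers matched, including 13848 of 15539 protein-coding ones (89.1%). Of these, 456 without a peak inside their gene, LIF and ADM among them, were matched by their start alone, and the strand of RefSeq genes was not given. After results had been seen 1 rule was added, because a name had gone to an identifier that starts at the far end of its gene. Such an identifier no longer takes a name that one with a peak inside the gene matches best, which moved 82 names, removed 15 and gave 19, with effects on the lists and the named genes. Gene names therefore mean the nearest annotated start, not a tested target, and 266 peaks had no annotation. The OAZ1 and RELL1 peaks instead carry the name of the gene they were annotated in, and ITGA7 peaks were taken by either name. Coordinates are those of the deposited annotation, counted from 1.

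Each line was tested apart, 4 siITGA7 against 4 siControl libraries, with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3, robust fit, TMM factors, default filter on low counts). Adjusted p values follow Benjamini and Hochberg over all tested peaks, with a threshold of 0.05. The difference between the lines was the interaction contrast in a fit of all 16 libraries. Log2 CPM values used a prior count of 2. Shares of counts in promoter peaks, depths and fragment sizes were compared with two-sided exact permutation tests over 70 arrangements, whose smallest possible p is 0.0286. Alternatives used DESeq2 1.42.0 and limma-voom (limma 3.58.1).

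Lists of genes were fixed before the data were examined, and their peaks were tested with limma's camera on log2 CPM with a correlation preset at 0.01. The adjustment ran over 44 tests, 22 lists in 2 lines. The lists were integrins, laminins and basement membrane, focal adhesion, mesenchymal and EMT drivers, epithelial junctions, keratinocyte differentiation, basal squamous identity, YAP/TEAD targets, AP-1 members, MAPK feedback and growth factor response, PI3K AKT mTOR, and DNA damage response and repair. The others were p53 targets and apoptosis, proliferation, chromatin regulators, nuclear lamina and LINC complex, inflammatory and NF-kB response, interferon response, hypoxia, fibroblast markers, endothelial and blood cell markers, and constitutive gene controls. Camera with an estimated correlation and fry were run beside it.

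Named genes followed a rule also fixed before the data were examined. It took every ITGA7 peak, and the 10 highest and 10 lowest called peaks per line among those of at least median level whose groups did not overlap, with 1 peak per gene. It also took up to 3 genes per list with the smallest p, the 5 genes with most called peaks in each direction, and the 5 peaks with the smallest interaction p. Genes of a list that stand outside this rule are named only where the list's called members are given in full or where the text says so. Some genes that the rule names are not reported here.

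The labels give the biological replicate number, BR1 to BR4, also as a batch that siControl and siITGA7 libraries of a line share. For that label it was taken as a pairing, though no shared day or culture is named. Deviations from the group means correlated between libraries of the same number at -0.0972, -0.00642, -0.0546 and -0.180 in Cal33 and at 0.0124, 0.00246, -0.00410 and -0.0315 in SAS, so the values themselves show no pairing. The fit without the number as a block was the main one, and the fit with it was an alternative. Counts of replicate libraries differed by more than sampling noise in every pair, with a chi-square per degree of freedom from 1.07 to 3.89, so each library counted once.

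The tests were tested on simulated counts with known changes. Few peaks were changed, in Cal33 93 tested ones by 1.5-fold and 89 by 2-fold, and all peaks of a line had 1 common spread. The real data hold more called peaks and libraries that stand apart, so the shares and false calls below need not carry over. In Cal33, 32.3% of peaks changed 1.5-fold and 71.9% of peaks changed 2-fold were called among 76243 simulated peaks, with 2 false calls. In SAS the shares were 17.6% and 61.4% among 43415 peaks, with 6 false calls. For the difference between lines they were 1.05% and 18.9% among 94781 peaks, with 1 false call.

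The alternatives were other scalings, filters, tools, thresholds, peak sets and fits, thinning to the smallest library, the batch block and leaving out each library. Trended offsets by peak class, the promoter share and the number of sequencing runs as covariates, the 1-run libraries alone, SAS peaks outside chromosome 12 and the correlation without each library were chosen after seeing the data. Other divisions of the libraries were also tested, all 35 per line for counts of peaks and lists. For the difference between lines 80 divisions were drawn, a number set for the run time after earlier draws had been seen. A first, smaller draw had left out divisions that mirror the real one in 1 line, and had adjusted lists per line. After its result was seen the draw was enlarged, these divisions were let in and the lists were adjusted over all 44 tests. The limits for deciding on an explanation were also made stricter after values were seen, for the matched promoter difference and for the position of single libraries. Checks of GC content and tests of sequence motifs were not run, since no genome sequence was used here.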

Results

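Accessible chromatin was profiled in Cal33 and SAS, established lines of head and neck squamous carcinoma without HPV, 48 h after transfection with a non-targeting siRNA (siControl) or siRNA against ITGA7 (siITGA7). ITGA7 encodes the alpha 7 chain of a laminin receptor, and the cells were grown in a laminin-rich matrix. Each of the 4 groups held 4 independent biological replicates with counts over a common set of peaks. The comparison asks where accessibility differs after ITGA7 depletion within each line. Total counts in peaks differed with the treatment, in opposite directions in the lines. Cal33 siControl libraries held 3980563 to 8367079 counts and siITGA7 libraries 8646532 to 13285086 (exact permutation p = 0.0286, the smallest that 4 against 4 can give). SAS siControl libraries held 1766033 to 4870187 counts and siITGA7 libraries 758590 to 1867047 (exact permutation p = 0.0571). Fragment sizes did not differ detectably between treatments (exact permutation p = 0.686 in Cal33 and 0.743 in SAS).

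**Figure D1:**
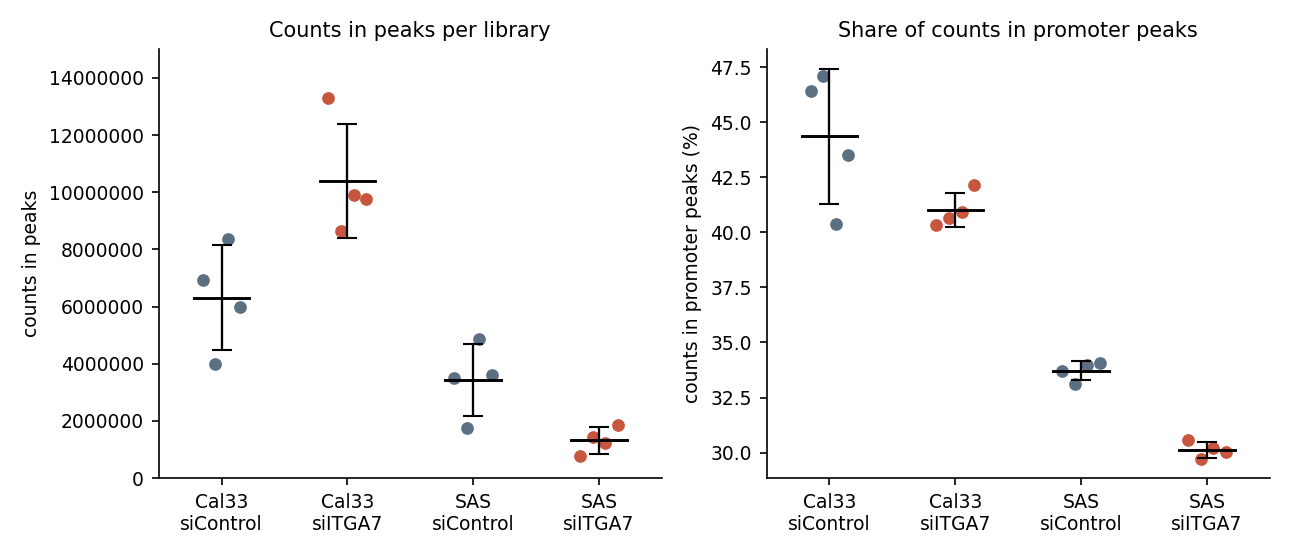
Total counts in peaks and share of counts in promoter peaks (%) for each of the 16 libraries, by line and treatment; points are libraries, horizontal bars group means and error bars SD (n = 4). Cal33 siITGA7 libraries (8646532 to 13285086 counts) lie above all Cal33 siControl libraries, and SAS siITGA7 libraries hold a smaller promoter share than all SAS siControl libraries.

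Accessibility at ITGA7 itself did not differ detectably in either line. The promoter peak of ITGA7 (chromosome 12, 55715814 to 55718019, GRCh38) had a log2 change of -0.12 ± 0.12 (SE, n = 4 per group; adjusted p = 0.552) in Cal33 and of -0.27 ± 0.18 (adjusted p = 0.395) in SAS. The other 3 ITGA7 peaks held too few counts to be tested, at most 13 in a Cal33 library and 22 in a SAS library. Since siRNA acts on the transcript, these values do not check the knockdown.

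In Cal33 the peak that rose most among the named peaks of at least median level lay in an intron of MAEA, a subunit of the CTLH ubiquitin ligase (chromosome 4, 1323625 to 1324846). Its level went from 3.10 ± 0.34 to 4.61 ± 0.22 log2 CPM (SD, n = 4), a log2 change of 1.48 ± 0.15 (SE; adjusted p = 2.29e-07). A peak upstream of CAV1, the main protein of caveolae (chromosome 7, 116521046 to 116521454), rose by 1.30 ± 0.20 (adjusted p = 0.000108), and a promoter-class peak of NMNAT2, an enzyme of NAD synthesis, rose by 1.19 ± 0.13 (adjusted p = 1.34e-06). The promoter-class peak of STXBP2, a protein of vesicle fusion, fell by 1.16 ± 0.16 (adjusted p = 2.67e-05). At each of these peaks all 4 siITGA7 libraries lay on 1 side of all 4 siControl libraries, which the naming rule required of the highest and lowest peaks. The calls of the peaks named in this paragraph held in every alternative in which single peaks were rechecked, and without any 1 library. Single peaks were not rechecked after thinning, in the fit of all 16 libraries, for autosomal peaks alone or with the sequencing runs as covariate.

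Of 75230 peaks tested in Cal33, 3397 were higher and 3514 lower after siITGA7. The median size was 0.65 on the log2 scale for the higher peaks and 0.56 for the lower ones, and 17.3% and 8.57% of them changed at least 2-fold. The groups did not overlap at 14.6% of tested peaks, against 2.86% by chance. The count moved with single libraries: 11346 without siControl replicate 3, 3868 without siControl replicate 1, 3233 without siITGA7 replicate 2 and 3154 without siITGA7 replicate 3. It was 4522 with DESeq2, 4418 after thinning to the smallest library and 3478 in the 5 libraries with 1 sequencing run each, and with total counts as library size 63.9% of calls were higher against 49.2%.

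Most of the promoter peaks called in Cal33 were lower. Of 14599 promoter peaks tested, 1450 (9.93%) were lower and 252 (1.73%) higher. Among introns 1726 of 33240 peaks were higher and 1072 lower, and among intergenic peaks 1148 of 20480 were higher and 685 lower. Promoter peaks took 44.3% ± 3.07 (SD, n = 4) of the counts of siControl libraries and 41.02% ± 0.787 of siITGA7 libraries, a difference that did not pass the test (exact permutation p = 0.114). It was -4.65 points without siControl replicate 3 (exact permutation p = 0.0286). Among libraries of 1 sequencing run the means were 41.9% (n = 2) and 40.6% (n = 3), with an exact permutation p of 0.4 where 0.1 is the smallest possible. Among those of 2 runs they were 46.8% (n = 2) and 42.1% (n = 1), which allows no p under 0.333.

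**Figure D2:**
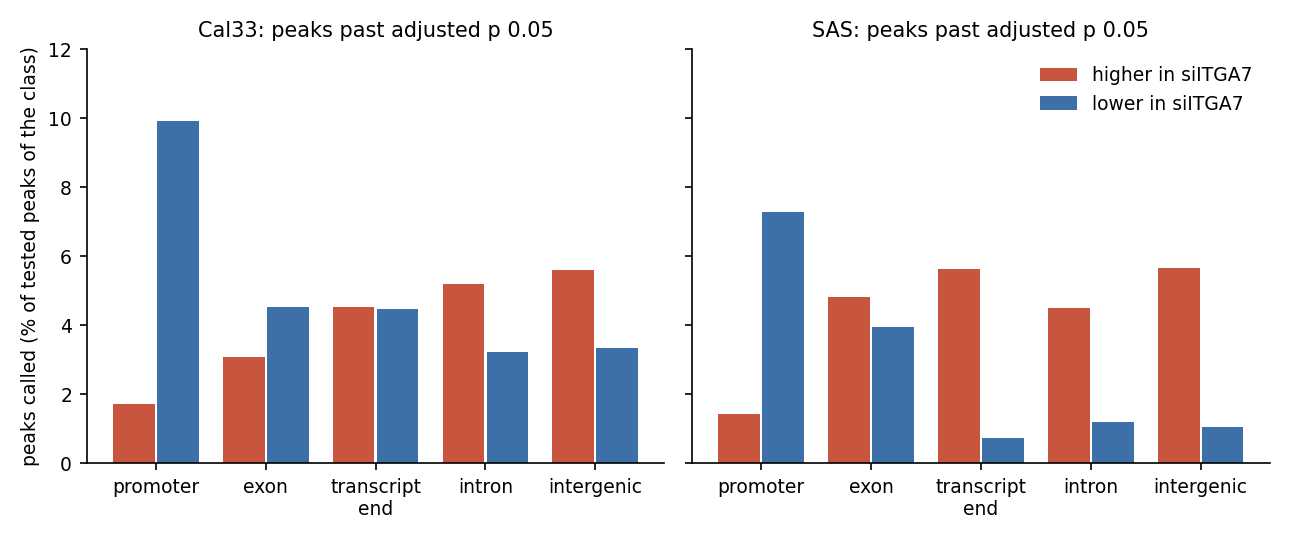
Peaks called higher or lower after siITGA7, as a percentage of the tested peaks of each annotation class, in Cal33 and SAS; bars start at 0. Among promoter peaks 9.93% were lower in Cal33 and 7.28% in SAS, more than were higher (1.73% and 1.42%).

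Of the 22 lists, only that of target genes of the co-activator YAP and TEAD transcription factors of the Hippo pathway was called in Cal33. Of 109 such peaks 10 were higher and 0 lower (12 and 0 adjusted over the list alone), at CRIM1, F3, FJX1, GADD45A, MYOF, NUAK2 and TEAD1. The list was called up (adjusted p = 0.0165), but at least 1 list was called in 11 of 35 divisions of the Cal33 libraries, the real one included. With an estimated correlation the call was lost (adjusted p = 0.475), as it was with promoter peaks only (adjusted p = 0.204). The rotation test fry, which does not compare a list with other peaks, gave an adjusted p of 0.0233, and 0.151 with the batch number as a block. In Cal33 fry also passed for the inflammatory (adjusted p = 0.00208), basal squamous (0.00822), hypoxia (0.0379), interferon (0.0380) and mesenchymal (0.0484) lists, and for none of the lists with the block (smallest adjusted p = 0.0791). FJX1, MYOF, NUAK2 and TEAD1 are named here after their values were seen. The peak upstream of GADD45A, a growth arrest and DNA damage gene (chromosome 1, 67682712 to 67683343), rose by 0.97 ± 0.13 (adjusted p = 1.33e-05). An intronic peak of CRIM1, a membrane protein that binds BMPs, rose by 0.93 ± 0.14 (adjusted p = 0.000120), and a peak near F3, the tissue factor of blood clotting, by 0.71 ± 0.14 (adjusted p = 0.00145).

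No other list passed in Cal33, and the nearest were hypoxia and epithelial junctions. Of 68 epithelial junction peaks 10 were higher and 1 lower (11 and 1 adjusted over the list alone; list adjusted p = 0.0917). They included a peak of PKP1, a desmosome protein (1.05 ± 0.21, adjusted p = 0.00219). That list passed with trended offsets (adjusted p = 0.00406), with these by class (0.00889) or with total counts (0.0388), and without siControl replicate 2 (0.0235). It did not pass with an estimated correlation (adjusted p = 0.555), promoter peaks only (0.731) or the batch number as a block (0.108). Of 49 hypoxia peaks 3 were higher and 9 lower (6 and 14 adjusted over the list alone; list adjusted p = 0.0720). The promoter of SLC2A1, the glucose transporter GLUT1, fell by 0.67 ± 0.11 (adjusted p = 0.000372), and a peak at NDRG1, a stress-response gene, fell by 1.34 ± 0.27 (adjusted p = 0.00171). The 3 higher peaks of this list lay at CAV1 and ADM, the latter named after its values were seen. The list passed with total counts (adjusted p = 0.0388) or promoter peaks only (0.0497), and without siControl replicate 2 (0.0153) or 3 (0.0162) or siITGA7 replicate 2 (0.0439), 3 (0.0208) or 4 (0.0330). It did not pass with an estimated correlation (adjusted p = 0.555), trended offsets by class (0.175) or the batch number as a block (0.0763).

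Inflammatory and NF-kB genes had 7 higher and 1 lower of 50 peaks (8 and 1 adjusted over the list alone; list adjusted p = 0.110), with LIF, a cytokine of the interleukin 6 family, at 0.93 ± 0.15 (adjusted p = 0.000130) and TNF at 1.30 ± 0.30 (adjusted p = 0.00514). That list passed with 1 value per gene (adjusted p = 0.0396), with trended offsets (0.0488), with these by class (0.0476), and without siControl replicate 2 (0.0437). It did not pass with an estimated correlation (adjusted p = 0.475), promoter peaks only (0.290) or the batch number as a block (0.157). Interferon response genes had 0 higher and 2 lower of 44 (0 and 1 adjusted over the list alone; list adjusted p = 0.150). Constitutive control genes had 0 higher and 2 lower of 17 (2 and 4 adjusted over the list alone; list adjusted p = 0.150). Proliferation genes had 1 higher and 6 lower of 39 (2 and 7 adjusted over the list alone; list adjusted p = 0.335), among them the promoter of MCM3, a replication helicase subunit, which fell by 0.48 ± 0.11 (adjusted p = 0.00636). The 1 higher peak lay in an intron of MCM4, another subunit of that helicase, and rose by 1.76 ± 0.39 (adjusted p = 0.00393) from a low level, -0.49 ± 0.31 log2 CPM (SD, n = 4).

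Adhesion and matrix genes gave no list call in Cal33. Integrins had 2 higher and 0 lower of 53 peaks, laminins and basement membrane 4 and 1 of 61, with 2 and 0 and then 7 and 2 adjusted over the list alone (list adjusted p = 0.468 for both). Focal adhesion genes had 6 higher and 4 lower of 107 peaks, the same adjusted over the list alone (list adjusted p = 0.688), including PTK2, the focal adhesion kinase (0.74 ± 0.15, adjusted p = 0.00176). Mesenchymal and EMT drivers had 1 higher and 2 lower of 56, the same adjusted over the list alone (list adjusted p = 0.688), with a peak near MMP9, a matrix protease, at 0.63 ± 0.14 (adjusted p = 0.00355). The lower peaks were a promoter-class peak of TGFBI (-0.44 ± 0.12, adjusted p = 0.0137) and a peak near SNAI1 (-0.84 ± 0.25, adjusted p = 0.0292).

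Genes of squamous identity and differentiation gave no list call in Cal33. Basal squamous genes had 5 higher and 2 lower of 64 peaks (6 and 3 adjusted over the list alone; list adjusted p = 0.468), and keratinocyte differentiation genes 0 and 3 of 51, the same adjusted over the list alone (list adjusted p = 0.676). With promoter peaks only the basal squamous list passed (adjusted p = 0.0119). It did not pass with an estimated correlation (adjusted p = 0.555), trended offsets by class (0.379) or the batch number as a block (0.510). A promoter-class peak of BNC1, a zinc finger protein of basal keratinocytes, rose by 0.63 ± 0.12 (adjusted p = 0.00114), and an intronic peak of JAG1, a Notch ligand, by 0.81 ± 0.17 (adjusted p = 0.00276). A promoter-class peak of TRIM29 fell by 0.55 ± 0.13 (adjusted p = 0.00799). An exon-class peak of TRIM29, added after its values were seen, rose by 0.43 ± 0.12 (adjusted p = 0.0184).

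Signalling and nuclear lists gave no call in Cal33 either. AP-1 members had 1 higher and 3 lower of 45 peaks (adjusted p = 0.666), and MAPK feedback genes 0 and 1 of 66 (adjusted p = 0.468). PI3K AKT mTOR genes had 4 and 2 of 46 (adjusted p = 0.925), where PIK3R1, a regulatory subunit of PI3 kinase, rose by 0.65 ± 0.12 (adjusted p = 0.000999). DNA damage genes had 1 and 3 of 35 (adjusted p = 0.936), p53 targets 0 and 2 of 34 (adjusted p = 0.468), chromatin regulators 4 and 3 of 65 (adjusted p = 0.989), and lamina and LINC genes 3 and 1 of 38 (adjusted p = 0.777). An intronic peak of BCL2L1, an inhibitor of apoptosis, fell by 0.67 ± 0.14 (adjusted p = 0.00355). Adjusted over the list alone, the counts were 4 and 3 for PI3K AKT mTOR, 6 and 3 for chromatin regulators, and the same as above for the other 5 lists.

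Markers of other cell types were tested in the same way. In Cal33 fibroblast markers had 0 higher and 1 lower of 21 peaks, the same adjusted over the list alone (list adjusted p = 0.925). Endothelial and blood cell markers had 1 and 2 of 25, with 2 and 2 adjusted over the list alone (list adjusted p = 0.989). An intronic-class peak near CDH5, the endothelial cadherin, rose by 0.82 ± 0.12 (adjusted p = 6.27e-05), while the promoter peak of CDH5, added after its values were seen, fell by 0.64 ± 0.15 (adjusted p = 0.00611). For DNA damage genes the median and the mean of the list were above 0 while the test pointed down. For PI3K AKT mTOR genes and chromatin regulators the mean alone, and for fibroblast markers the median alone, was above 0 with a test pointing down.

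In SAS the largest named rises lay at a peak near LOC124902630, an uncharacterised locus, and in an intron of SNTG2, a syntrophin of the dystrophin complex. The SNTG2 peak (chromosome 2, 1221432 to 1222147) went from 3.87 ± 0.27 to 5.90 ± 0.31 log2 CPM (SD, n = 4), a log2 change of 2.09 ± 0.17 (SE; adjusted p = 2.10e-21). The LOC124902630 peak (chromosome 11, 11246551 to 11246937) rose by 2.31 ± 0.18 (adjusted p = 9.08e-23). A promoter-class peak of SETD5, a SET domain protein, rose by 1.62 ± 0.18 (adjusted p = 1.28e-12), and a peak at the end of HMGB1, an abundant chromatin protein, by 1.60 ± 0.15 (adjusted p = 1.50e-17). The promoter-class peak of IGSF9B, a synaptic adhesion protein (chromosome 11, 133956658 to 133957433), fell by 1.25 ± 0.26 (adjusted p = 0.000314). The promoter of KIAA1191 fell by 0.97 ± 0.20 (adjusted p = 0.000253).

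Of 43600 peaks tested in SAS, 1762 were higher and 1305 lower after siITGA7. The median size was 0.85 on the log2 scale for the higher peaks and 0.56 for the lower ones, and 33.4% and 4.67% changed at least 2-fold. The groups did not overlap at 11.6% of tested peaks, against 2.86% by chance. The count was 1977 without siITGA7 replicate 4, 459 after thinning to the smallest library, 1036 with DESeq2, 1396 for peaks with at least 50 counts on average and 6577 with no filter, and the share that was higher, 57.5%, was 71.7% after thinning, 74.7% with DESeq2, 67.8% with trended offsets by class and 35.3% with no filter. With the promoter share of each library as a covariate, which separates the SAS groups completely, edgeR called 0 peaks, with 2010 at an unadjusted p under 0.05, and no other tool was run with that covariate.

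Peaks in the first 40 Mb of chromosome 12 rose together in SAS. The 5 genes with most called higher peaks were all on this chromosome, led by GRIN2B, a glutamate receptor subunit, with 36 of 77 tested peaks higher, and RN7SKP162, a 7SK pseudogene, with 36 of 64. On this chromosome 4 windows of 5 Mb, all between 10 and 40 Mb, were picked for a median SAS change above 0.3. In them 329 of 912 tested peaks were higher and 11 lower, counts that this choice favours. Against other autosomes the median shift there was 0.41 on the log2 scale for peaks outside promoters and 0.076 for the 91 promoter peaks. Outside these windows 156 of 2223 peaks of the chromosome were higher. Over the whole of chromosome 12, 15.5% of tested SAS peaks were higher, against 4.67% in Cal33.

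**Figure D3:**
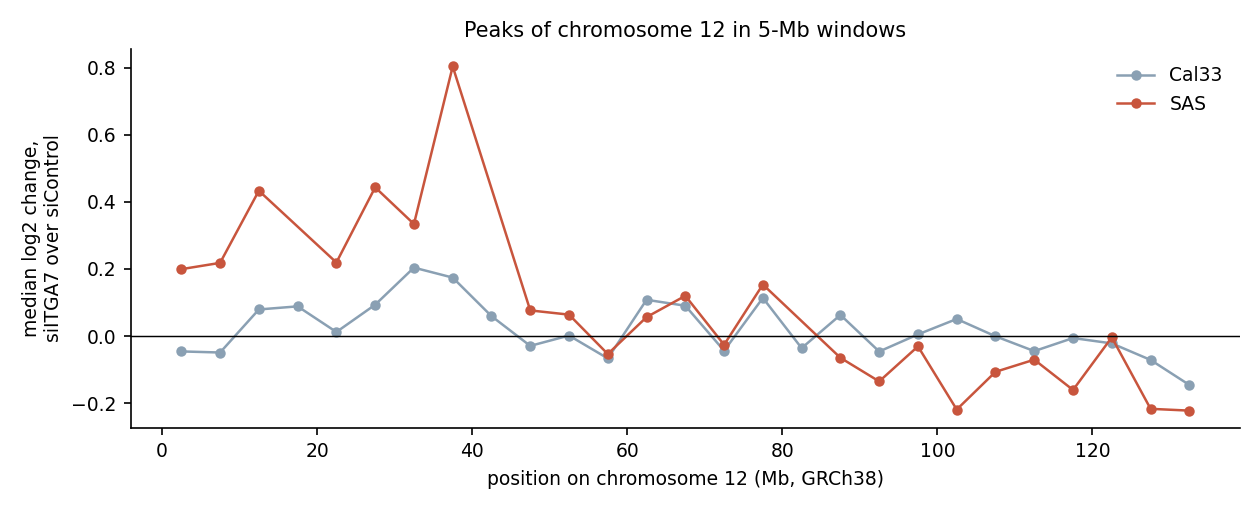
Median log2 change (siITGA7 over siControl) of tested peaks in 5 Mb windows along chromosome 12, in megabases, for SAS and Cal33. In SAS the windows from 25 to 40 Mb and from 10 to 15 Mb reach 0.33 to 0.80, while Cal33 reaches at most 0.20 on the chromosome.

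Most of the promoter peaks called in SAS were lower as well. Of 12258 promoter peaks tested, 892 (7.28%) were lower and 174 (1.42%) higher, while 756 of 16815 intronic peaks were higher and 201 lower, and 566 of 9980 intergenic peaks were higher and 105 lower. Promoter peaks took 33.7% ± 0.422 (SD, n = 4) of the counts of siControl libraries and 30.1% ± 0.364 of siITGA7 libraries (exact permutation p = 0.0286, the smallest possible). With the batch number as a block the exact p was 0.125, the smallest that 4 pairs allow. Each SAS library had 1 sequencing run, and whether they shared it is not given in the sources used here. The change of the share in Cal33 minus that in SAS was 0.258 points (permutation p = 0.908).

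Peaks of endothelial and blood cell marker genes were called up as a list in SAS, through 1 gene. Of 37 peaks 9 were higher and 0 lower (14 and 0 adjusted over the list alone; list adjusted p = 0.0200). With an estimated correlation the list was not called (adjusted p = 0.555), nor with 1 value per gene (adjusted p = 0.751). At least 1 list was called in 5 of 35 divisions of the SAS libraries, the real one included. All 9 higher peaks lay at VWF, the von Willebrand factor gene of endothelium and platelets, on chromosome 12, where the peak from 5996297 to 5997634 rose by 0.65 ± 0.14 (adjusted p = 0.000960). With fry the list did not pass (adjusted p = 0.0842), and the VWF peak lost its call with no filter (adjusted p = 0.0519). Leaving out siControl replicate 3 or 4 or siITGA7 replicate 2, 3 or 4 also ended the call, with an adjusted p of 0.0650, 0.0506, 0.0902, 0.128 and 0.0720.

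No other list passed in SAS. Keratinocyte differentiation genes had 2 higher and 0 lower of 26 peaks (3 and 0 adjusted over the list alone; list adjusted p = 0.227), and passed with promoter peaks only (adjusted p = 0.0497). They did not pass with an estimated correlation (adjusted p = 0.555), trended offsets by class (0.188) or the batch number as a block (0.238). Epithelial junction genes had 4 higher and 0 lower of 46, the same adjusted over the list alone (list adjusted p = 0.304), with a peak near PKP1 at 1.01 ± 0.20 (adjusted p = 0.000121). Basal squamous genes had 3 and 0 of 30, the same adjusted over the list alone (list adjusted p = 0.356), with an intronic peak of EGFR, the epidermal growth factor receptor, at 1.35 ± 0.35 (adjusted p = 0.00542). Chromatin regulators had 4 and 2 of 35 (5 and 3 adjusted over the list alone; list adjusted p = 0.936). Among them were peaks of CHD4, a remodeller of the NuRD complex (1.81 ± 0.34, adjusted p = 6.48e-05), ARID1A, a subunit of SWI/SNF (1.59 ± 0.31, adjusted p = 0.000100), and KAT2A, a histone acetyltransferase (1.05 ± 0.20, adjusted p = 6.76e-05). The CHD4 peak lay on chromosome 12 (6583084 to 6583449) and the KAT2A peak on chromosome 17 (42116820 to 42118364). Their 5 Mb windows had median SAS changes of 0.218 and 0.266. Inflammatory genes had 2 and 0 of 36, the same adjusted over the list alone (list adjusted p = 0.666).

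Signalling lists in SAS held 1 or 2 called peaks each. AP-1 members had 1 higher and 1 lower of 39 peaks (1 and 0 adjusted over the list alone; list adjusted p = 0.468), with FOSL1, an AP-1 subunit, at 1.48 ± 0.23 (adjusted p = 9.87e-07). YAP/TEAD targets had 1 and 1 of 83 (0 and 1 adjusted over the list alone; list adjusted p = 0.777), where a peak of AMOTL2, an angiomotin that binds YAP, fell by 0.58 ± 0.14 (adjusted p = 0.00207). PI3K AKT mTOR genes had 0 and 2 of 32 (0 and 4 adjusted over the list alone; list adjusted p = 0.517), with the promoter of IRS2, an insulin receptor substrate, falling by 0.60 ± 0.13 (adjusted p = 0.000487). MAPK feedback genes had 0 and 1 of 49 (list adjusted p = 0.688), interferon genes 0 and 1 of 23 (list adjusted p = 0.503) and DNA damage genes 0 and 1 of 20 (list adjusted p = 0.335), all the same adjusted over the list alone. Hypoxia genes had 1 and 0 of 39, the same adjusted over the list alone (list adjusted p = 0.989), and p53 targets 0 and 1 of 26, with 0 and 0 adjusted over the list alone (list adjusted p = 0.468).

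Adhesion, lamina and growth lists in SAS were likewise not called. Integrins had 0 higher and 1 lower of 31 peaks, with 0 and 0 adjusted over the list alone (list adjusted p = 0.835), and focal adhesion genes 1 and 1 of 75, with 0 and 0 adjusted over the list alone (list adjusted p = 0.989). Laminins and basement membrane had 1 and 1 of 43, the same adjusted over the list alone (list adjusted p = 0.925). Mesenchymal and EMT drivers had 2 and 1 of 48, the same adjusted over the list alone (list adjusted p = 0.760), with a peak of ZEB2, a repressor of epithelial genes, at 1.46 ± 0.21 (adjusted p = 4.97e-08). Lamina and LINC genes had 1 and 1 of 28 (3 and 2 adjusted over the list alone; list adjusted p = 0.763), where the promoter of TPR, a nuclear pore protein, fell by 0.54 ± 0.11 (adjusted p = 0.000309). Proliferation genes had 1 and 2 of 32 (1 and 3 adjusted over the list alone; list adjusted p = 0.462), where a peak of MCM6, a replication helicase subunit, fell by 0.92 ± 0.21 (adjusted p = 0.00183). Fibroblast markers had 0 and 0 of 13, also adjusted over the list alone (list adjusted p = 0.855), and constitutive controls 1 and 0 of 18, the same adjusted over the list alone (list adjusted p = 0.925). For focal adhesion and hypoxia genes the median and mean were above 0 while the test pointed down, and for constitutive controls the mean alone was above 0.

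The lines differed in their response at single loci. Of the 5 peaks with the smallest interaction p, 3 lay at MAEA, at OAZ1 and in an intron of RELL1. The others lay between genes on chromosome 1 and on a random contig of that chromosome, with differences of 1.68 and 1.73. The MAEA peak rose in Cal33 and had a log2 change of 0.088 ± 0.12 in SAS (adjusted p = 0.741), a difference of 1.51 ± 0.21 (interaction adjusted p = 1.01e-06). The promoter of OAZ1, an inhibitor of polyamine synthesis (chromosome 19, 2269088 to 2271939), fell by 0.47 ± 0.13 in Cal33 (adjusted p = 0.0187) and rose by 0.90 ± 0.10 in SAS (adjusted p = 5.36e-12), with an interaction adjusted p of 1.60e-06. The peak in an intron of RELL1 (chromosome 4, 37604553 to 37604952) rose by 1.91 ± 0.18 in SAS (adjusted p = 2.12e-16) and was too weak to be tested in Cal33 alone, with a difference of -3.35 ± 0.46 (interaction adjusted p = 1.01e-06).

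**Figure D4:**
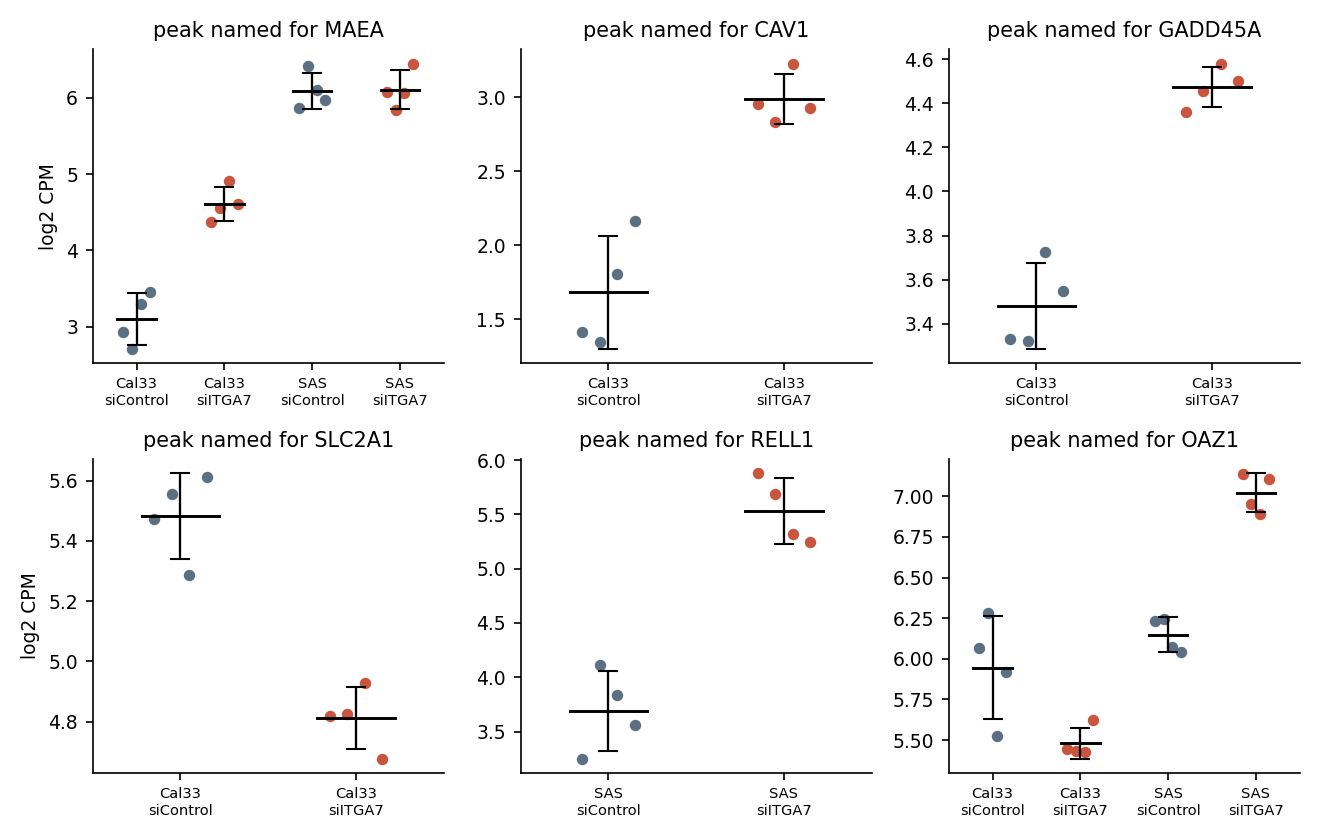
Log2 CPM of single libraries at peaks of MAEA and OAZ1 in both lines, of RELL1 in SAS and of CAV1, GADD45A and SLC2A1 in Cal33; points are libraries, bars means and error bars SD (n = 4), and the y scale differs between panels. MAEA goes from 3.10 to 4.61 in Cal33 and from 6.09 to 6.11 in SAS, while OAZ1 goes down in Cal33 and up in SAS.

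The interaction was called at 722 of 94918 peaks, 466 with a more positive change in Cal33 and 256 with a more negative one. Of the 553 of these tested in both lines, 492 had opposite signs, and 41 were called in both lines in opposite directions. Picking peaks by their difference between the lines favours opposite signs. Over all 38393 peaks tested in both lines, 58.6% had the same sign. The count was 1495 without Cal33 siControl replicate 3, and 470, 446 and 421 without SAS siControl replicate 3, SAS siControl replicate 4 and SAS siITGA7 replicate 4. It was 1125 with trended offsets, 1441 with no filter and 478 with DESeq2, and the share more positive in Cal33, 64.5%, was 40.4%, 85.1% and 50.6% under these. That share was 41.6% with DESeq2 size factors and 41.5% with trended offsets by class.

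Promoter and other peaks also changed together in the lines more than apart. Among 38393 peaks tested in both, 192 were lower in both lines against 77.4 for independent lists, and 113 were higher in both against 53.4. Peaks higher in Cal33 and lower in SAS numbered 19 against 70.4, and the reverse 24 against 58.7. Among promoter peaks 153 were lower in both against 100.5. Across peaks, which are not independent replicates, the log2 changes of the lines correlated at 0.201 (Pearson) and 0.219 (Spearman).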

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

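No test in this part was chosen after its result was seen. The difference between the lines was called at 722 peaks, by the interaction test on all 16 libraries. Among named peaks the signed log2 change was the more positive in Cal33 at ITGA11 (1.56), MAEA (1.51), DIAPH2 (1.48), LOC105374988 (1.43), LIF (1.403), ANO2 (1.30), LOC105373760 (1.28), CRIM1 (1.22), S100A16 (1.203), DNAH5 (1.201), PHF11 (1.18), NMNAT2 (1.11), F3 (1.01), CDH5 (0.98), GADD45A (0.94), LOC105376156 (0.92) and PTK2 (0.88). The same held for a peak without a gene name on chromosome 1 (1.68) and a peak on a random contig of that chromosome (1.73).

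The signed log2 change was the more positive in SAS at LOC124902630 (Cal33 minus SAS, -4.05), LINC02813 (-3.35), the intron of RELL1 (-3.35), HNRNPA3 (-2.46), KCNH2 (-2.45), CYP11B2 (-2.30), SETD5 (-2.26), NDRG1 (-2.14), LOC101927914 (-2.10), EGFR (-1.98), OAZ1 (-1.26), BAK1 (-0.99) and CD68 (-0.69).

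At some named peaks 1 library stood far from the other 3 of its group. The gap to the nearest library, as a share of the group's range of log2 CPM, passed Dixon's 95% limit in 17 of 332 groups tested (5.12%), and chance alone gives about 1 in 20. In Cal33 siControl libraries these were TRIM29 (0.834, replicate 4), HDAC4 (0.943, replicate 3), CD68 (0.966, replicate 3), NFKBIA (0.845, replicate 2) and MIR4785 (0.885, replicate 2). In Cal33 siITGA7 replicate 4 it was OAZ1 (0.902).

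In SAS siControl libraries the peaks were AMOTL2 (0.870, replicate 3), TNS4 (0.953, replicate 1) and S100A9 (0.900, replicate 3). In SAS siITGA7 libraries they were LOC124902630 (0.932), KIAA1191 (0.943), FERMT1 (0.948) and HERC6 (0.985), all in replicate 1, SETD5 (0.837, replicate 2), FBXO15 (0.835, replicate 3), RHEB (0.8294, replicate 4) and TPR (0.864, replicate 4).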

How the results depend on the processing

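The tests with trended offsets by class, with covariates or with 1-run libraries only, and the correlation without 1 library, were chosen after the result was seen. Calls in Cal33 numbered 6911, and 4522 with DESeq2, 4418 after thinning and 3478 with 1-run libraries only. They numbered 2218 at an adjusted p under 0.01, 890 with a log2 change of at least 1 as well as 0.05, and 3154 to 11346 without 1 library. With the promoter share as covariate Cal33 had 8170 calls, 3901 of them shared with the main fit. With the number of sequencing runs as covariate it had 9206, 6844 of them shared. Calls in SAS numbered 3067, and 6577 with no filter, 1396 at a mean of at least 50 counts, 1036 with DESeq2, 459 after thinning, 1461 at 0.01, 649 with the log2 limit, and 1977 to 3796 without 1 library. With the promoter share as covariate edgeR called 0 SAS peaks (2010 at an unadjusted p under 0.05), since that share parts the groups; without that covariate DESeq2 called 1036 and limma-voom 3107. Interaction calls numbered 722, and 1125 with trended offsets, 1230 with these by class, 1441 with no filter, 478 with DESeq2, 180 at 0.01, 438 with the log2 limit, and 421 to 1495 without 1 library. Where fewer peaks, libraries or counts, or a stricter limit, do not explain such a difference, the cause was not tested.

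The share of higher calls moved from 57.5% in SAS to 35.3% with no filter, 74.7% with DESeq2, 71.7% after thinning and 67.8% by class, and in Cal33 from 49.2% to 63.9% with total counts. For the interaction it moved from 64.5% to 41.6% with size factors, 40.4% with trended offsets, 41.5% by class, 85.1% with no filter, 46.2% at a mean of 50 counts, 50.6% with DESeq2 and 47.7% with limma-voom. The median of all peaks moved by over 0.1 only for the interaction with no filter (0.14).

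With the replicate block the calls numbered 5431 in Cal33, 2575 in SAS and 527 for the interaction. The block gave a promoter share change of -3.59 points in SAS with an exact p of 0.125, the smallest that 4 pairs allow. With the block 4 of 85 named Cal33 peaks and 7 of 66 named and called SAS peaks lost their call, and none of 5 between lines. It also changed the test of the SAS promoter share and the fry tests in Cal33, and it changed no list call of camera. Peaks named outside the rule, such as those of FJX1, TEAD1 and ADM, and the counts per list and class were not rechecked with the block. The Cal33 promoter share change ran from -4.65 to -2.42 points without 1 library, and the SAS one from -3.79 to -3.45. List calls numbered 1 in Cal33, and 0 with an estimated correlation, 2 with promoter peaks only, 2 with 1 value per gene, 3 with total counts, 3 with trended offsets, 3 by class, and 1 to 4 without 1 library. In SAS 1 list was called, and 0 with an estimated correlation or 1 value per gene, 1 other list with promoter peaks only, and 0 to 1 without 1 library. The correlation between the lines stayed between 0.140 and 0.201 in all settings, and between 0.161 and 0.214 without 1 library.

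Of the named peaks that were called, 33 of 85 in Cal33 and all 66 in SAS lost their call under at least 1 rechecked alternative. Leaving aside the promoter share as covariate, these numbers were 29 and 31. Without some library 26 and 30 lost their call, while none of the 5 between lines lost it in any of these. Single peaks were not rechecked after thinning, in the fit of all 16 libraries, for autosomal peaks alone or with the sequencing runs as covariate, so more calls may be lost. After thinning, 413 of all 3067 SAS calls were kept. With the promoter share as covariate, 14 SAS peaks changed sign, none of them called there. These were DIAPH2 (0.71), FOSL1 (-0.83), FOSL2 (0.076), MRE11 (0.88), GADD45A (-2.06), POLR2A (-0.87), VWF (-0.38), JUP (-1.003), TNS4 (-0.35), TGFBR1 (0.11), TOP2A (-0.81), RNA5SP354 (-0.41), PARP11-AS1 (-0.22) and ANO2 (0.0060). Lists that were not called changed sign in 12 of 43 cases with promoter peaks only, 7 with 1 value per gene, 6 with trended offsets and 7 by class. GC offsets and motif groups were not run. Depth and replicate spread limit what was detectable. Of simulated 1.5-fold changes 32.3% were called in Cal33, 17.6% in SAS and 1.05% between lines. Few peaks were changed there and all peaks of a line had 1 common spread, so the shares in the real data may differ.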

Other observations

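The test of library depth was chosen after its result was seen. Peaks on unplaced or random contigs rose in SAS more often than those of any chromosome: 86 of 174 tested were higher and 0 lower, against 29 higher and 6 lower of 280 in Cal33. On chromosome 17, 154 of 2470 SAS peaks were higher and 21 lower, and on chromosome X, 124 of 1604 Cal33 peaks were lower and 38 higher.

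The median log2 change of promoter minus other peaks was -0.150 in Cal33, where the promoter share of counts did not pass its test (exact permutation p = 0.114), and -0.210 in SAS. Depth was higher after siITGA7 in Cal33 and lower in SAS, while the difference of promoter minus other peaks was negative in both. That argues against a depth effect of 1 direction as the cause in both lines. After thinning to 1 depth the difference was -0.176 in Cal33 and -0.180 in SAS. Thinning removes counts from all peaks of a library in the same proportion, which keeps its promoter share, so these values do not decide on depth. Promoter and other peaks matched on read density still differed by -0.201 in SAS (-0.214 to -0.191 without 1 library), which argues against lower enrichment over background as the whole cause there, but by -0.114 in Cal33 (-0.179 to -0.0714), where that stays open. In Cal33 the peaks that vary with the promoter share among siControl libraries correlated with the siITGA7 change at 0.103 (0.0648 to 0.151 without 1 siControl library), with 0.255 over promoter peaks, 0.0336 over other peaks and -0.00683 when the siITGA7 libraries were used instead, so that an axis already there among controls stays open, for promoter peaks most of all. A bias by GC content was not tested in either line. In SAS a treatment effect stays open beside it, beside depth in that line alone and beside a part from more background reads. In Cal33 it stays open beside GC content, depth in that line alone, lower enrichment and the axis among controls.

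In the 4 windows between 10 and 40 Mb of chromosome 12, picked for a median SAS change above 0.3, SAS peaks rose. That rise was 0.335 larger in other peaks than in promoter peaks (0.324 to 0.352 without 1 library, in the same windows). A change of copy number in the siITGA7 cultures would move both alike, so that value argues against it. The windows were picked on the same changes, though, and only 91 of their 912 peaks were promoter peaks, so the gap may be overstated. More background reads over a region of high copy number would give such a gap, and may be the cause. Reads in weak peaks there were 1.63-fold more frequent in SAS than in Cal33 siControl libraries, relative to other autosomes. In 2 other windows of the genome the median also passed the same limit. They lay on chromosome 1 from 140 Mb (0.934, 19 of 27 peaks higher) and on chromosome 2 from 90 Mb (0.501, 9 of 23). The value on chromosome 1 was the highest of any window, above those of chromosome 12 (at most 0.803). No biological explanation was tested.

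Cal33 siControl replicate 3 lay at 0.517 on a scale from the other siControl libraries (0) to the siITGA7 libraries (1), on peaks called without it. Each other library was placed in the same way on peaks called without it, the siITGA7 libraries at 0.734 to 1.01 (0.879 ± 0.122, SD, n = 4) and the other siControl libraries at 0.0635 to 0.344. No siITGA7 library lay among the siControl libraries, as a swap within the line would need. A single wrong label may still be the cause, and a value between the groups does not settle it. The siControl replicates 1 and 2, with 2 sequencing runs each, lay at 0.138 and 0.0635, and replicates 3 and 4, with 1 run each, at 0.517 and 0.344. The siITGA7 library with 2 runs, replicate 4, lay at 0.830, among the others of its group. The promoter shares of siControl replicates 1, 2, 3 and 4 were 46.4%, 47.1%, 40.4% and 43.5%. Lower shares thus went with higher positions. Replicate 3 was also the deepest siControl library, and its share lay in the siITGA7 range, 40.3% to 42.1%. Among siITGA7 libraries this order did not hold, as replicate 1, with the lowest share, lay lowest. A mixed sample, a difference between cultures and a part of the promoter share, the depth or the sequencing runs in the position of siControl replicate 3 were not tested.

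Other divisions of the libraries tested whether chance could give these counts. In 1 of 35 divisions, the real one, Cal33 reached 6911 calls, the highest other 6, and in 1 of 35 SAS reached 3067, the highest other 98. As 1 of 35 is the smallest share possible, this argues against chance in both lines but does not exclude it. Nor can these divisions tell the treatment from the depth, which also parts the Cal33 groups. Among the 8 divisions that part all 4 batch pairs, the highest other was 0 in Cal33 and 16 in SAS, and 1 of 8 is the smallest share possible. For the interaction only the real one of 80 divisions reached 722, though its count alone does not exclude chance. The highest other, 685, is close. It kept Cal33 as labelled and set SAS siControl replicate 4 with siITGA7 replicates 2, 3 and 4 against the rest, so it also holds real changes of the lines. The next, 472, kept 3 of 4 libraries of each Cal33 group and exchanged 3 of 4 of each SAS group, so it holds them as well, and the one after it gave 65. The correlation between lines, 0.201 on mean log2 CPM, was reached by 1 of 100 divisions, the highest other being 0.155. For lists chance is not excluded: 11 of 35 divisions in Cal33 called at least the 1 list of the real one (highest other 3), and 5 of 35 in SAS (highest other 1).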
